A study of Cereibacter sphaeroides with 18 samples.

How the data were processed

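Expression was measured on 18 arrays hybridised with biotin-labelled cDNA made from total RNA of the purple bacterium Rhodobacter sphaeroides, listed in the labels under its newer name Cereibacter sphaeroides. The cultures grew in the light in Sistrom's minimal medium and were harvested in the early post-exponential phase. The deposited values are log2 expression per probe set, normalized between arrays by the authors, with 1 column per array and 2 decimals. RMA and limma are named in the submitters' processing notes without a version or a role, and the background correction and the handling of replicates are not stated. The values ran from 6.04 to 14.83, none was missing, and the medians of the arrays lay between 8.55 and 8.65. The number of arrays per group limits the precision of every comparison. Background was not analysed here, so a fold or log2 difference from a group whose level lay below the lower quartile of its arrays (7.90 to 7.99) is a lower bound.

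All 4145 probe sets were tested. The platform annotation paired 537 of them with exactly 1 gene each and gave none for the other 3608, so only 13.0% of the measurements could be named. These 537 probe sets stood for 512 genes by Entrez identifier and 497 symbols, 15 of which were shared by 2 loci. 10 genes had several probe sets. None of the Entrez identifiers and 475 of the symbols were found in the reference annotation, so locations are not given. Gene functions mentioned in the text are background knowledge, not part of the data.

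Arrays were grouped by the organic substrate and nitrogen source in the labels, which gave 6 groups. One linear model with a coefficient per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom and 1.85 prior degrees of freedom. Differences were tested two-sided by limma's moderated test with Benjamini-Hochberg adjustment over all 4145 probe sets. A probe set was called at an adjusted p under 0.05, and a second count also asked for an absolute log2 difference of at least 1. There were 12 comparisons: the mean of the 5 substrates against the reference, each substrate against the reference, each substrate against the mean of the other 4 substrates, and limma's moderated F test for any difference between the 5 substrates. The 10 differences between pairs of substrates were computed from the same model. Against the reference, nitrogen source, culture volume and H2 production differ together, and so does the carbon source outside succinate, so the comparisons with the reference cannot separate them. The labels give each array a cell density, mostly different within a group, but do not state that replicates were separate cultures, and a p-value then measures only the spread between samples. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

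26 gene lists were defined by patterns on gene symbols: nitrogenase, Rnf electron transport, nitrogen regulation and assimilation, uptake hydrogenase and maturation, light harvesting and reaction centre, bacteriochlorophyll and carotenoid synthesis, Calvin cycle, polyhydroxybutyrate, Entner-Doudoroff and pentose phosphate entry, xylose use, glycerol use, sugar transport, lactate use, C4-dicarboxylate transport, TCA cycle, gluconeogenesis, ethylmalonyl-CoA pathway, respiratory chain, ATP synthase, ribosomal proteins, flagella and chemotaxis, heat shock and protein quality, oxidative stress, iron and molybdenum uptake, anaerobic respiration, and gas vesicles. Patterns on product names were not applied, so a list could hold only genes with a symbol in the platform annotation. A gene with several probe sets entered a list at the one with the highest mean. 15 lists with at least 3 genes were tested with limma's camera against the other named genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. 7 lists with 1 or 2 genes are described without a test. 4 lists (Rnf electron transport, lactate use, C4-dicarboxylate transport and the ethylmalonyl-CoA pathway) were not analysed here. Each list's members were also counted with p-values adjusted over the list alone. Camera was repeated with a correlation estimated from the data, and limma's fry was run beside it.

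The genes named in the text came from a rule. It took 36 symbols chosen in advance, of which 16 were measured and the other symbols were not analysed here. It also took the 10 largest called rises and falls of the mean of the substrates over the reference, among probe sets whose 16 H2-producing arrays all lay on one side of both reference arrays, and the 6 largest rises and falls for succinate in the same way. For each substrate against the other 4 it took the 5 largest rises and the 3 largest falls among probe sets whose arrays all lay beyond every array of the other substrates. From each list and comparison it took up to 4 called members with the largest differences. The rule named 125 probe sets of 123 genes. The calls were tested on simulated data with 200 changed probe sets: 92.5% of the log2 changes of 1 were recovered for the mean of the substrates over the reference, 86.6% for succinate over the reference and 97.0% for glycerol against the other substrates.

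The alternatives tried were quantile normalization, centring of the arrays on their medians, leaving out the dimmest 25% of probe sets, testing only probe sets with 1 gene, a variance prior with trend and robust settings, array weights, only the arrays of the groups compared, a replicate block, each array left out in turn, stricter thresholds, cell density as a covariate, equal weight per array, a comparison with succinate alone, and for lists an estimated correlation, fry and the median over a gene's probe sets. Leaving out the 4 sugar arrays harvested below 250 Klett units, leaving glycerol out of the other substrates and taking all probe sets as the background of the lists were chosen after seeing the data. When 1 of the 2 glycerol or reference arrays was left out, the remaining array was assumed to vary like the other groups. Simulated groups with no difference between conditions but with shared reference arrays gave the overlap to be set beside the comparisons with the reference. Random splits of the 16 H2-producing arrays were drawn for the comparisons between substrates. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.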

Results

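The series holds 18 arrays of Rhodobacter sphaeroides, a purple bacterium that makes H2 through nitrogenase when it grows in the light without ammonium. 16 arrays came from H2-producing cultures with glutamate as nitrogen source: 3 were fed lactate, 3 succinate, 4 glucose, 4 xylose and 2 glycerol. The other 2 arrays came from larger cultures fed succinate and NH4+ that did not make H2 and served as reference. Each array gave log2 expression for 4145 probe sets, of which 537 carry the name of 1 gene.

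Cell density at harvest, as the labels give it, was 325 ± 8.66 Klett units (SD, n = 3) with lactate, 325 ± 15 (n = 3) with succinate, 309 ± 9.90 (n = 2) with glycerol and 285 ± 21.2 (n = 2) in the reference. The sugar cultures were more uneven, with 256 ± 58.0 (n = 4) for glucose and 262 ± 41.3 (n = 4) for xylose. In a principal component analysis of all probe sets the first component held 32.2% of the variance and placed the reference arrays at -31.5 and -32.6. The second held 21.9% and placed the glycerol arrays at -21.9 and -20.9. Within groups, Pearson's r between arrays, taken across probe sets that are not independent replicates, was lowest between glucose arrays (0.931) and highest between the reference arrays (0.992).

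The mean of the 5 substrates was set against the reference to ask what H2-producing cultures shared whatever they were fed. All 11 measured nitrogenase genes rose, and the structural genes of molybdenum nitrogenase rose most. nifK (probe set 1429) was at least 59.4-fold higher (log2 5.89 ± 0.50, SE, 16 arrays against 2, adjusted p = 1.43e-06), nifH (1431) was higher by log2 5.78 ± 0.21 (adjusted p = 5.55e-10) and nifD (1430) 34.7-fold (5.12 ± 0.38, adjusted p = 4.97e-07). The activator gene nifA (1437) rose by less, with a log2 difference of 0.43 ± 0.07 (adjusted p = 0.00033). The TCA cycle and ribosomal protein lists were higher as well, and the light harvesting, pigment and heat shock lists were lower, the last with 4 of 9 genes called. With an estimated correlation none of these lists was called (adjusted p = 0.342 each).

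Of the other nitrogenase genes, nifW (1418), nifX (1426), nifV (1419, homocitrate synthase), nifS (1420, cysteine desulfurase), nifN (1427) and nifB (1436) rose by log2 2.22 to 3.69, and all 16 H2-producing arrays lay above both reference arrays for nifW, nifX, nifV, nifS and nifN. The count of 11 was the same adjusted over the list alone, and leaving out any 1 array left all 11 called. The list's median was 2.85 (camera adjusted p = 0.000152, and adjusted p = 0.342 with an estimated correlation). In the list of nitrogen regulation and assimilation, gltB (2047, glutamate synthase) rose by 0.83 ± 0.12 (adjusted p = 0.000149), 1 of 3 genes in both counts, and the list was not called (adjusted p = 0.470). glnA (3253, glutamine synthetase) differed by 0.30 ± 0.13 and was not called (adjusted p = 0.0720).

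The uptake hydrogenase list held only maturation genes. 4 of its 5 members rose, also adjusted over the list alone: hypB (1394) 4.91-fold (adjusted p = 1.43e-06), hypD (1399) 2.20-fold, hypE (1400) at least 2.09-fold and hypA (1393) at least 1.99-fold. The list itself was not called against the other named genes (median 1.06, adjusted p = 0.0703) but was against all probe sets (adjusted p = 0.00263). In the TCA cycle 6 of 7 genes rose in both counts: sucC (1866, succinyl-CoA synthetase) by log2 2.68 ± 0.28, sdhA (1875, one of 2 loci for succinate dehydrogenase) by 2.64 ± 0.24 and sucD (1865) by 1.57 ± 0.25, beside mdh (1867, malate dehydrogenase) at 3.04-fold. The median of the list was 1.57 (adjusted p = 0.0102, and adjusted p = 0.342 with an estimated correlation).

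Of 45 ribosomal protein genes 41 rose and 1 fell, over all probe sets and adjusted over the list alone, with a median of 0.93 (adjusted p = 9.49e-09, and adjusted p = 0.342 with an estimated correlation). rpsG (2630) rose by log2 1.94 ± 0.16 (adjusted p = 1.33e-06) and rpsN (2648) by 1.77 ± 0.18 (adjusted p = 6.57e-06). The member that fell was rpsU (1616), at -0.61 ± 0.20 (adjusted p = 0.0259), and its adjusted p was 0.163 without reference replicate 2. Of the ATP synthase genes 3 of 4 rose in both counts, led by atpA (3231, one of 2 loci) at 1.68 ± 0.12, with a list median of 0.80 that was not called (adjusted p = 0.10). In the respiratory chain 6 of 13 genes rose in both counts, among them ccoP (1587, cbb3 oxidase) at 0.74 ± 0.10, and the list was not called (median 0.40, adjusted p = 0.158).

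Among photosynthesis genes, 5 of 7 light harvesting and reaction centre genes fell in both counts (median -0.43, adjusted p = 0.00101, and adjusted p = 0.342 with an estimated correlation). pufX (1123) fell by log2 0.78 ± 0.12 (adjusted p = 0.000200) and pufL (1125, reaction centre) by 0.43 ± 0.08 (adjusted p = 0.000701). The 5 probe sets of pufA differed, from -0.62 to -0.09, with 3 called. 11 of 17 bacteriochlorophyll and carotenoid genes fell in both counts (median -0.38, adjusted p = 2.66e-06, and adjusted p = 0.342 with an estimated correlation), among them crtB (1142, phytoene synthase) at -0.77 ± 0.19. These falls leaned on the reference arrays: without reference replicate 1 or 2, 4 and 2 pigment genes and 3 light harvesting genes each time were called, and crtB had an adjusted p of 0.0916 without reference replicate 1.

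4 of 9 heat shock and protein quality genes fell in both counts, including lon (3749, protease) at -0.82 ± 0.16 (adjusted p = 0.00122) and the chaperones clpB (2309) at -1.01 ± 0.25 and dnaK (2074) at -0.81 ± 0.28. The list's median was -0.12 (adjusted p = 0.00714, and adjusted p = 0.342 with an estimated correlation). It was not called against all probe sets (adjusted p = 0.110). clpB was not called without reference replicate 2 (adjusted p = 0.0698) nor dnaK without reference replicate 1 (adjusted p = 0.195), and without either reference array only 1 member of the list was called. Outside the lists, htpx (1444, membrane protease) fell by 1.44 ± 0.23 (adjusted p = 0.000231), tspO (1141) by 0.96 ± 0.16 (adjusted p = 0.000339) and ftsW (3039, cell division) by 0.70 ± 0.13 (adjusted p = 0.000870), each with all 16 H2-producing arrays below both reference arrays. grxC (2095, glutaredoxin) at -0.94 and hslO (2108, chaperone Hsp33) at -0.74 fell too, but without reference replicate 2 their adjusted p was 0.0855 and 0.139.

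In the iron and molybdenum list 1 of 8 genes rose and 2 fell in both counts: bfr (4296, one of 2 loci for bacterioferritin) rose by 0.74 ± 0.10, and feoB (2738, ferrous iron uptake) was 2.56-fold lower (adjusted p = 0.000409), while modC (4838, molybdate transport) at -0.18 lost its call without either reference array or glycerol replicate 1 (adjusted p = 0.25 without reference replicate 1). That list was not called (median 0.02, adjusted p = 0.244). In the Entner-Doudoroff list 3 of 5 genes rose in both counts, among them pgi (3679) by 0.65 ± 0.08, and the list was not called (median 0.28, adjusted p = 0.433). This rise was not shared: per array the list's median was 1.07 to 1.34 with xylose and glycerol, at most 0.14 with glucose and below the reference in all 6 lactate and succinate arrays. None of the 3 xylose genes was called in either count (median 0.43, adjusted p = 0.926). In the sugar transport list 2 of 4 genes rose in both counts, ugpB (4242) and ugpA (4241), which belong to a transporter for sn-glycerol 3-phosphate, and ugpA was not called without reference replicate 1 (adjusted p = 0.167), 1 of the 4 being called without either reference array. 9 of 20 flagellar genes rose in both counts, but 3 without reference replicate 1 and 2 without reference replicate 2. Both rises of the mean were mainly those of glycerol, since outside it 0 of 4 sugar transport genes were called over the reference with any substrate and the flagellar medians of the other 14 H2-producing arrays did not exceed 0.10. Single flagellar genes could still rise elsewhere: fliN (923) was called higher with succinate and with xylose. Both calls of fliN ended without reference replicate 2. Neither list was called (medians 0.14 and 0.15, adjusted p = 0.906 and 0.896). Beside rbsK the sugar transport list held only ugpE, ugpA and ugpB. Its members called below with succinate, glucose, xylose and glycerol are all ugp genes, so those calls concern glycerol 3-phosphate transport and not sugars.

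The 7 lists of 1 or 2 genes gave the same counts adjusted over the list alone. glpD (3613, glycerol-3-phosphate dehydrogenase) rose by at least 0.86 ± 0.10, which came from glycerol (11.95 against 7.96 to 8.08 with the other substrates and 7.95 in the reference), and glpK (3605, glycerol kinase) was lower at -0.24 ± 0.07, the latter with an adjusted p of 0.114 without reference replicate 1. eno (3433, enolase) rose by 0.88 ± 0.14 and phaC (1892, polyhydroxybutyrate synthase) fell by 0.51 ± 0.08. rpoE (3624), from the oxidative stress list, fell by 0.34 ± 0.05, and chrR (1993) from the same list was not called. Of the anaerobic respiration genes, the sensor kinase gene dorS (3993) fell by 0.76 ± 0.15, and dorR (3994) rose by 0.20 ± 0.05 with an adjusted p of 0.0834 without reference replicate 2. The gas vesicle genes gvpJ (4537) and gvpA (4530) fell by 0.37 ± 0.06 and 0.23 ± 0.09, the latter with an adjusted p of 0.264 without reference replicate 2. Neither Calvin cycle gene (cbbX, cbbR) was called.

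In total 1776 probe sets were called, 911 higher and 865 lower, of which 266 differed by a log2 of at least 1 (172 higher, 94 lower). Leaving out reference replicate 1 or 2 lowered the count to 1094 and 859. Of the 71 named probe sets called here, 22 lost their call without 1 array, each of them without a reference array. Those that did so without either reference array included pufM (1124), bchY (1133), rpsU, clpB, dnaK, grxC, hslO, glpK, dorR, ugpA and modC. The share called higher was 51.3% on the deposited values, 39.9% with arrays centred on their medians and 45.5% after quantile normalization.

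**Figure D1:**
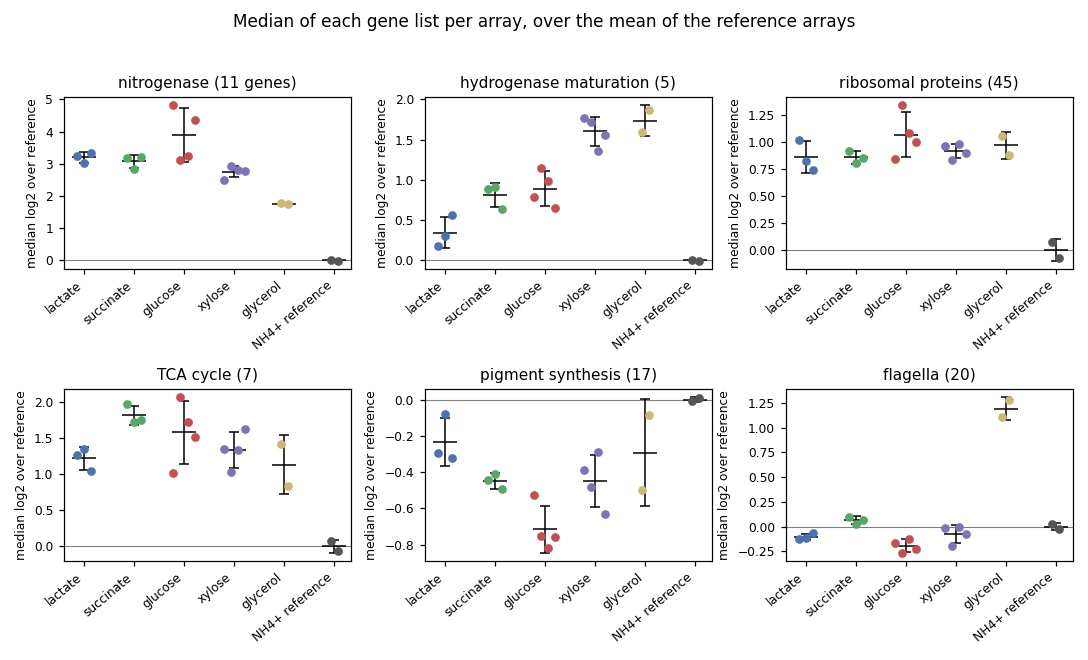
Median over the genes of 6 lists (log2, vertical axes) of each array minus the mean of the 2 reference arrays, by group on the horizontal axes; points are arrays and black bars are group means with SD. The nitrogenase medians of the 16 H2-producing arrays lie from 1.75 upwards, against 0.01 and -0.01 in the reference, and the flagellar medians reach 1.11 and 1.28 with glycerol and at most 0.10 elsewhere.

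Succinate with glutamate (3 arrays) was set against succinate with NH4+ (2 arrays) to hold the carbon source constant. All 11 nitrogenase genes rose, nifH (1431) 64.5-fold (log2 6.01 ± 0.25, SE, adjusted p = 4.47e-09), nifK (1429) at least 72.3-fold (adjusted p = 9.80e-06) and nifD (1430) 42.7-fold (5.42 ± 0.46). Of the TCA cycle genes, sucC (1866) rose 9.83-fold, sdhA (1875, one of 2 loci) 8.34-fold (3.06 ± 0.29) and sucD (1865) 4.68-fold (2.23 ± 0.31). Genes that fell included htpx (1444, membrane protease, 2.86-fold), feoB (2738, ferrous iron uptake, at -1.39 ± 0.28), gcvT (3127, glycine cleavage, at -1.15 ± 0.25), crtB (1142, phytoene synthase, at -1.15 ± 0.23) and tspO (1141, at -1.11 ± 0.20). In these genes and in nifW (1418, at least 15.9-fold) and nifX (1426, 13.2-fold) all 3 succinate arrays lay on one side of both reference arrays. clpB (2309, chaperone) at -1.24 ± 0.31 also fell, with an adjusted p of 0.0619 without reference replicate 2.

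By list, nitrogenase genes (median 3.07, adjusted p = 1.25e-05), 6 of 7 TCA cycle genes (median 1.82, adjusted p = 0.00170), 36 of 45 ribosomal protein genes (38 adjusted over the list alone, median 0.85, adjusted p = 3.04e-09) and 3 of 4 ATP synthase genes (median 0.85, adjusted p = 0.0473) rose. With an estimated correlation the adjusted p was 0.243 for each of these 4 lists, and the ATP synthase call also ended with array weights (adjusted p = 0.0701), with density as a covariate (0.0808), without the dimmest 25% of probe sets (0.0522) and without the 4 sugar arrays below 250 Klett units (0.0579). 9 of 17 pigment genes (10 adjusted over the list alone, median -0.42, adjusted p = 1.20e-05), 4 of 7 light harvesting genes (5 adjusted over the list alone, median -0.39, adjusted p = 0.00374) and 3 of 9 heat shock genes (median -0.17, adjusted p = 0.00625) fell, again with adjusted p = 0.243 with an estimated correlation. 2 Entner-Doudoroff genes fell (list median -0.17, adjusted p = 0.0483, and adjusted p = 0.256 with an estimated correlation). Against all probe sets neither the Entner-Doudoroff nor the heat shock list was called (adjusted p = 0.193 and 0.0634). Without reference replicate 1 the pigment count was 3 and the Entner-Doudoroff count 0. Without reference replicate 2 the pigment count was 4, the light harvesting count 2 and the heat shock count 1, and without succinate replicate 3 the pigment count was 5. 4 of 5 hydrogenase maturation genes rose (2 without reference replicate 2), though their list was not called (adjusted p = 0.0771). Where no second count is given, the count adjusted over the list alone was the same.

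Over all probe sets 1206 were called in this comparison, 637 higher and 569 lower, and 244 differed by a log2 of at least 1 (157 higher, 87 lower). The count was 762 without reference replicate 1 and 597 without reference replicate 2.

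Each of the other 4 substrates was also set against the reference, which tells what each condition changed relative to the cells without H2 production. Nitrogenase genes rose with lactate, glucose and xylose, all 11 in each, with list medians of 3.20, 3.88 and 2.74 (camera adjusted p = 1.67e-05, 2.32e-05 and 0.000196). With an estimated correlation the adjusted p was 0.231, 0.309 and 0.289. With glycerol 7 of the 11 rose (8 adjusted over the list alone), nifH (1431) 29.8-fold (adjusted p = 1.42e-08, n = 2), and the list was not called (adjusted p = 0.0618). nifB (1436) and nifA (1437) with glycerol were not called (adjusted p = 0.263 and 0.741). Ribosomal protein genes rose with each of these substrates: 36 of 45 with lactate (40 adjusted over the list alone), 41 with glucose, 40 with xylose (41 adjusted over the list alone) and 40 with glycerol. The adjusted p of the list was 5.44e-09, 8.54e-09, 1.11e-08 and 9.38e-07, and 0.231, 0.309, 0.272 and 0.280 with an estimated correlation.

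TCA cycle genes rose with lactate, glucose and xylose, 6 of 7 in each (adjusted p = 0.00525, 0.0123 and 0.00913, and adjusted p = 0.231, 0.309 and 0.289 with an estimated correlation), and 5 rose with glycerol (3 without reference replicate 2), where the list was not called (adjusted p = 0.0985). Hydrogenase maturation genes rose with xylose and glycerol, 4 of 5 in each (medians 1.67 and 1.69, adjusted p = 0.00958 and 0.0430, and adjusted p = 0.272 and 0.280 with an estimated correlation), with hypB (1394) 8.50-fold higher with xylose. 4 of 5 also rose with glucose and 1 with lactate, where the list was not called. Among light harvesting genes 2 of 7 fell with lactate (3 adjusted over the list alone, 1 without lactate replicate 3 or reference replicate 2), 5 with glucose (3 without either reference array), 4 with xylose (2 without reference replicate 1) and 4 with glycerol, with list p-values adjusted to 0.00525, 0.00273, 0.00293 and 0.00334, and adjusted p = 0.231, 0.309, 0.272 and 0.280 with an estimated correlation. Pigment genes fell with glucose, 11 of 17 (12 adjusted over the list alone, median -0.63, adjusted p = 2.61e-08), and with xylose, 9 of 17 (11 adjusted over the list alone, adjusted p = 7.35e-06, 4 without reference replicate 1, 3 without reference replicate 2 and 5 without xylose replicate 2 or 4), with adjusted p = 0.309 and 0.272 with an estimated correlation. With lactate 1 and with glycerol 4 pigment genes fell (0 and 1 adjusted over the list alone), and both lists were called (adjusted p = 0.00324 and 0.00516, and adjusted p = 0.289 and 0.365 with an estimated correlation). The lactate count was 0 without lactate replicate 3 or either reference array, and the glycerol count was 0 without glycerol replicate 1 or reference replicate 2 and 1 or 2 without any of several other arrays.

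Substrate-dependent lists differed between these comparisons. 4 of 5 Entner-Doudoroff genes rose with xylose (adjusted p = 0.00772) and with glycerol (adjusted p = 0.0442), and 2 fell with lactate (adjusted p = 0.0160, and 0 without reference replicate 1), with adjusted p = 0.272, 0.280 and 0.231 with an estimated correlation. The 3 xylose genes rose with glucose (median 2.13) and with xylose (median 1.91), although the list was called in neither (adjusted p = 0.0630 and 0.0646). With lactate xylF (2081, xylose-binding protein) fell by 2.05 ± 0.29 (adjusted p = 0.000186) in a called list (adjusted p = 0.00660, and adjusted p = 0.231 with an estimated correlation). With glycerol 18 of 20 flagellar genes rose (median 1.19, adjusted p = 2.94e-07, and adjusted p = 0.280 with an estimated correlation), glpD (3613) rose by at least log2 4.00 ± 0.13 (adjusted p = 5.90e-11) and ugpB (4242) rose by 1.87 ± 0.09. With glucose 9 flagellar genes fell (10 fell and 1 rose adjusted over the list alone, with 2 left without reference replicate 1, 4 without reference replicate 2 and 5 without lactate replicate 2 or 3, succinate replicate 1 or glucose replicate 2 or 4). With lactate 4 fell (0 without reference replicate 1, 1 without lactate replicate 1 or 2). The 2 lists had p-values adjusted to 8.65e-05 and 0.000655, and adjusted p = 0.309 and 0.279 with an estimated correlation. With xylose 1 flagellar gene rose and 1 fell (neither adjusted over the list alone, and each lost its call without a reference array), in a list with adjusted p = 0.0168, and adjusted p = 0.337 with an estimated correlation. Heat shock genes fell with lactate (2 of 9, adjusted p = 0.00332), xylose (3, adjusted p = 0.0210) and glycerol (3, adjusted p = 0.0167), with adjusted p = 0.231, 0.289 and 0.280 with an estimated correlation. With glucose lon (3749) and clpX (1063) were called lower, but both lost their calls without either reference array. The median of the heat shock genes was 0.19 higher with glucose than with lactate, with 1 of 9 called higher. The lactate count was 1 without reference replicate 1 or lactate replicate 3 and 0 without reference replicate 2, the xylose count 1 and 0 without reference replicates 1 and 2, and the glycerol count 1 without glycerol replicate 1 or either reference array.

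The counts of called probe sets were 1162 for lactate (645 higher, 517 lower), 1747 for glucose (914 and 833), 1570 for xylose (832 and 738) and 1551 for glycerol (762 and 789). A log2 of at least 1 was reached by 247, 343, 339 and 333. Without reference replicate 2 the counts were 562, 996, 874 and 841, and 698 were left for lactate without reference replicate 1 and 1014 for glycerol without glycerol replicate 1. With arrays centred on their medians the share called higher was 43.9%, 39.2%, 39.6% and 33.3%, against 55.5%, 52.3%, 53.0% and 49.1% on the deposited values, and after quantile normalization it was 45.7%, 47.5%, 45.5% and 38.3%. In all 5 comparisons of a substrate with the reference, 358 probe sets were called higher and 267 lower, including 120 and 18 with a gene name. The 5 comparisons share the same 2 reference arrays. Simulated groups without differences but with that sharing gave at most 0 in 20 simulations. Without differences few calls can arise at all, so these counts cannot tell how much of the overlap the sharing gave. The mean correlation of the log2 differences across probe sets, which are not independent replicates, was 0.788 against 0.599 in the simulations. Sharing alone thus gave a sizeable correlation, while the mean covariance was 0.312 against 0.0224. 68 probe sets were called in opposite directions for different substrates.

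Among the H2-producing cultures, 987 of 4145 probe sets (23.8%) differed between the 5 substrates by limma's moderated F test, 157 of them with a gene name, and in 298 the substrate means spanned a log2 of at least 1. Between pairs, glycerol differed from glucose in 750 probe sets, from lactate in 670, from succinate in 517 and from xylose in 478. Lactate and succinate differed in only 17. Glucose and xylose differed in 107, glucose and lactate in 571, xylose and lactate in 417, glucose and succinate in 453, and xylose and succinate in 266. Each substrate was then compared with the mean of the other 4 to find what was particular to it. These 5 comparisons are not independent of each other, since their differences add up to 0, so differences between pairs are given beside them.

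**Figure D2:**
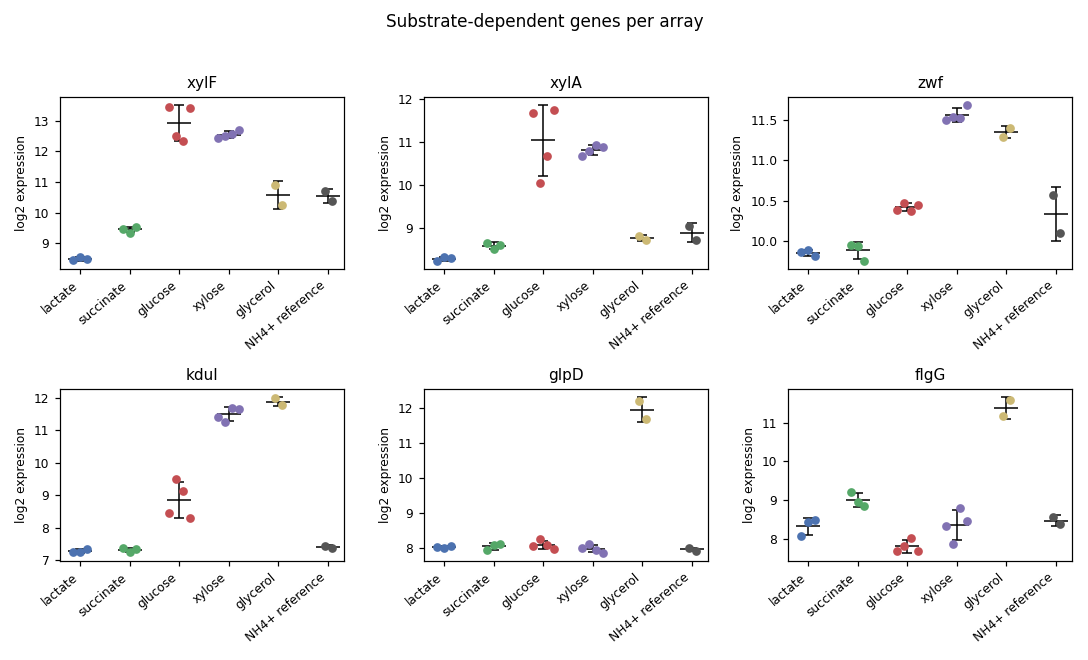
Log2 expression per array (vertical axes) of xylF, xylA, zwf, kduI, glpD and flgG in the 5 H2-producing groups and the reference (horizontal axes); points are arrays and black bars are group means with SD. glpD lies at 12.20 and 11.69 with glycerol and at most at 8.24 in the other groups, and kduI lies above 11 with xylose and glycerol and at most at 7.45 with lactate, with succinate and in the reference.

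With lactate (3 arrays) genes for sugar breakdown and hydrogenase maturation were lower than the mean of the other 4 substrates, but were not called against succinate alone. xylF (2081, xylose-binding protein) was 7.40-fold lower (log2 -2.89 ± 0.20, SE, adjusted p = 4.54e-07), with a level of 8.49 ± 0.06 (SD, n = 3) against 12.93 ± 0.59 (n = 4) with glucose and 12.55 ± 0.12 (n = 4) with xylose. thiE (1542) and thiM (1543, thiamine synthesis), thiB (2292, thiamine-binding protein) and ispD (3778, isoprenoid synthesis) were higher by 0.78 ± 0.12, 0.60 ± 0.08, 0.62 ± 0.07 (adjusted p = 2.24e-05) and 0.73 ± 0.12, and crtA (1144, spheroidene monooxygenase) by 0.77 ± 0.13 (adjusted p = 0.00106). In thiE, thiM, thiB, ispD and xylF all 3 lactate arrays lay beyond every array of the other substrates, and crtA was named through its list.

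4 of 5 hydrogenase maturation genes were lower (median -0.88, adjusted p = 0.000231, and adjusted p = 0.0968 with an estimated correlation), hypB (1394) by -1.26 ± 0.17 and hypD (1399) by -1.03 ± 0.14. 4 of 5 Entner-Doudoroff genes were lower (median -0.90, adjusted p = 9.99e-06, and adjusted p = 0.0670 with an estimated correlation), among them eda (3588, one of 2 loci) by -1.22 ± 0.12, zwf (3677) by -0.94 ± 0.08 and pgl (3678) by -0.90 ± 0.07. The 3 xylose genes were lower (median -1.51, adjusted p = 0.000171, and adjusted p = 0.0968 with an estimated correlation). 16 of 20 flagellar genes were lower (16 lower and 1 higher adjusted over the list alone, median -0.40, adjusted p = 5.97e-10, and adjusted p = 0.0968 with an estimated correlation). 3 of 17 pigment genes were higher (7 adjusted over the list alone, median 0.21, adjusted p = 0.000890, and adjusted p = 0.419 with an estimated correlation). The flagellar call rested on glycerol: against the other substrates without glycerol the median was -0.07 (adjusted p = 0.232), and against succinate alone the Entner-Doudoroff median was -0.02 (adjusted p = 0.719). Between lactate and succinate 0 genes of the hydrogenase, Entner-Doudoroff, xylose, flagellar and pigment lists were called. Of the pigment genes 0 were called between glycerol and lactate either, while 6 were lower with glucose and 4 with xylose than with lactate. None of the 11 nitrogenase genes was called. Over all probe sets 485 were called, 200 higher and 285 lower, 79 of them by a log2 of at least 1 (14 and 65), 293 without lactate replicate 2 and 257 without lactate replicate 3.

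With succinate (3 arrays) expression stood out least, and the 16 named probe sets called were all lower. 9 of them lost their call without 1 array. 4 of 5 genes of the Entner-Doudoroff list were lower than with the other 4 substrates: eda (3588, one of 2 loci) by log2 -1.21 ± 0.12 (SE, adjusted p = 1.10e-05), zwf (3677, glucose-6-phosphate dehydrogenase) by -0.91 ± 0.08 (adjusted p = 2.41e-06), pgl (3678, 6-phosphogluconolactonase) by -0.86 ± 0.07 and pgi (3679) by -0.64 ± 0.07. xylF (2081) was lower by -1.68 ± 0.20 (adjusted p = 0.000110). The Entner-Doudoroff list had a median of -0.86 (adjusted p = 1.31e-08) and held with an estimated correlation (adjusted p = 0.0118). However, 0 of its genes were called between succinate and lactate. Several smaller falls came from glycerol being among the others: without it flgH (942) was higher by 0.33 (adjusted p = 0.00567), fliQ, glpK, glpD and ugpB were no longer lower, and the flagellar list was higher (0.22, adjusted p = 7.76e-13). That list was not tested there with an estimated correlation. By pairs 10 of its 20 genes were lower with glucose than with succinate, but 0 were called between succinate and lactate or xylose.

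The 3 xylose genes were lower (median -1.13, adjusted p = 0.000157, and adjusted p = 0.122 with an estimated correlation), but xylA (2077) and xylB (2078) lost their calls without succinate replicate 2 (adjusted p = 0.142 and 0.0918), and without any 1 of the succinate arrays only 1 of the 3 was called. In the sugar transport list 2 of 4 were lower (3 adjusted over the list alone, median -0.20, adjusted p = 0.0434, and adjusted p = 0.122 with an estimated correlation), the glycerol 3-phosphate transporter genes ugpB (4242) and ugpE (4240). Only 1 was called without any 1 succinate array or without most other arrays, and against the other substrates without glycerol the median was 0.03 (adjusted p = 0.556). The TCA cycle list was higher as a whole (median 0.26, adjusted p = 0.00557, and adjusted p = 0.335 with an estimated correlation) with 0 of 7 genes called and 2 adjusted over the list alone, and it was not called against the other substrates without glycerol (0.20, adjusted p = 0.106). None of the 11 nitrogenase genes was called. In all, 144 probe sets were called, 56 higher and 88 lower, 39 of them by a log2 of at least 1 (9 and 30). Without succinate replicates 1, 2 and 3 the count was 85, 67 and 76. The share called higher was 38.9%, but 54.7% with centred arrays and 49.3% after quantile normalization.

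With glucose (4 arrays) genes for xylose use and several nitrogenase genes were higher than the mean of the other 4 substrates, while flagellar and pigment genes were lower. xylF (2081) was 6.35-fold higher (log2 2.67 ± 0.18, SE, adjusted p = 6.87e-07), xylA (2077, xylose isomerase) 3.76-fold and xylB (2078, xylulokinase) 3.65-fold. nifB (1436) was higher by 2.18 ± 0.29 (adjusted p = 0.000171), nifE (1428) by 2.00 ± 0.24 (adjusted p = 6.78e-05), both in the assembly of the nitrogenase cofactor, and nifS (1420) by 1.56 ± 0.25 (adjusted p = 0.000772). flgM (891, anti-sigma factor of the flagellar regulon) was 2.96-fold lower (-1.56 ± 0.16) and flgG (943, flagellar rod) at least 2.76-fold (-1.46 ± 0.14), and in pigment synthesis crtA (1144) was lower by -0.86 ± 0.12 (adjusted p = 0.000177) and bchF by -1.10 at probe set 1164, 1 of its 5 probe sets.

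No difference in xylF was called between the sugars (-0.38, xylose minus glucose, adjusted p = 0.523), and it was 4.44 ± 0.24 higher with glucose than with lactate. 6 of 11 nitrogenase genes were higher (the same number adjusted over the list alone, median 0.57, adjusted p = 0.000424, and adjusted p = 0.356 with an estimated correlation), among them nifA (1437) by 0.35 ± 0.06. nifH (1431) by 0.52 ± 0.16 and nifN (1427) by 1.13 ± 0.28 lost their calls without glucose replicate 4 (adjusted p = 0.172 and 0.0716), nifN also without glucose replicate 1 and nifH without any 1 of 15 arrays, and without glucose replicate 1 or 4 the count was 4. nifD and nifK were not called (adjusted p = 0.217 and 0.751). The 2 glucose cultures of lowest density (212 and 204 Klett units) held the highest nifH, 14.71 and 14.59, against 13.66 and 13.80 in the cultures at 325 and 282. Without the 4 sugar arrays below 250 Klett units the nitrogenase median was 0.07 (adjusted p = 0.604), while nifB (1.54, adjusted p = 0.0118), nifE, nifS and nifA stayed called. Against xylose alone 3 nitrogenase genes were higher, against lactate 3 and against succinate 4.

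**Figure D3:**
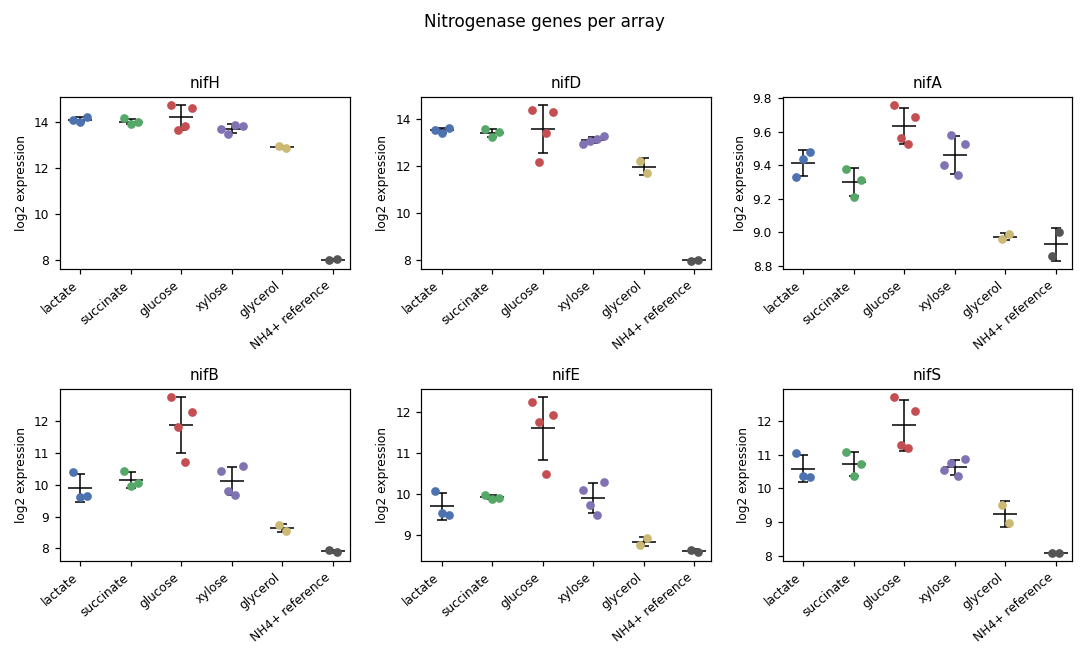
Log2 expression per array (vertical axes) of 6 nitrogenase genes in the 5 H2-producing groups and the reference (horizontal axes); points are arrays and black bars are group means with SD. nifH lies between 12.84 and 14.71 in the H2-producing arrays and near 8.00 in the reference, and nifB, nifE and nifS reach their highest values with glucose.

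16 of 20 flagellar genes were lower with glucose (17 adjusted over the list alone, median -0.44, adjusted p = 7.17e-16, and adjusted p = 0.0683 with an estimated correlation), and 10 were lower than with succinate alone, but only 1 was lower than with lactate and 0 were called between glucose and xylose. 8 of 17 pigment genes were lower (12 adjusted over the list alone, median -0.34, adjusted p = 2.13e-05, and adjusted p = 0.268 with an estimated correlation). Against lactate, succinate and glycerol alone 6, 5 and 8 of them were lower, but against xylose only 1. The 3 xylose genes were called as a list (median 1.91, adjusted p = 0.000100, and adjusted p = 0.112 with an estimated correlation). 6 of 45 ribosomal protein genes were higher (median 0.20, adjusted p = 0.00398, and adjusted p = 0.536 with an estimated correlation), but 2 without glucose replicate 2 or 4 and 3 without glycerol replicate 2. 3 of 5 Entner-Doudoroff genes were lower (4 adjusted over the list alone, median -0.24, adjusted p = 0.0211, and adjusted p = 0.268 with an estimated correlation), 1 without glucose replicate 3 or 4 or glycerol replicate 2. This list was not called against the others without glycerol (-0.02, adjusted p = 0.521) or with array weights (adjusted p = 0.114). Against succinate alone these genes were higher (median 0.34, adjusted p = 0.00519). In the sugar transport list the 3 ugp genes were lower (median -0.22, adjusted p = 0.0168, and adjusted p = 0.112 with an estimated correlation), a call that ended against the other substrates without glycerol (-0.02, adjusted p = 0.730). Over all probe sets 608 were called, 307 higher and 301 lower, 55 of them by a log2 of at least 1 (21 and 34), and 396 without glucose replicate 4.

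With xylose (4 arrays) genes of the Entner-Doudoroff list, of xylose use and of hydrogenase maturation were higher than the mean of the other 4 substrates. uxaC (1374, glucuronate isomerase) was at least 5.54-fold higher (log2 2.47 ± 0.20, SE, adjusted p = 1.19e-06), xylF (2081) 4.57-fold (2.19 ± 0.18, adjusted p = 1.43e-06), eda (3588, one of 2 loci) 2.87-fold (1.52 ± 0.11, adjusted p = 1.80e-07), zwf (3677) 2.27-fold (1.18 ± 0.07, adjusted p = 2.99e-08) and pgl (3678) 2.24-fold (1.16 ± 0.06, adjusted p = 1.26e-08). The other eda locus (4253) was not called for any substrate. hypB (1394) was higher by 0.99 ± 0.15 and hypA (1393) by 0.85 ± 0.12. Against glucose alone, xylose cultures had zwf higher by 1.14, eda (3588) by 1.45, uxaC by 1.80 and kduI (1368, an isomerase of uronate breakdown) by 2.65. Between xylose and glycerol 0 of 5 Entner-Doudoroff and 0 of 5 hydrogenase maturation genes were called (medians -0.15 and -0.04, glycerol minus xylose), so these rises were not particular to xylose. Nor was that of the xylose genes, since 0 of 3 were called between xylose and glucose (median -0.38, xylose minus glucose).

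4 of 5 Entner-Doudoroff genes (median 1.16, adjusted p = 1.23e-10), the 3 xylose genes (median 1.63, adjusted p = 3.85e-06) and 4 of 5 hydrogenase maturation genes (median 0.81, adjusted p = 1.71e-05) were higher, and these lists held with an estimated correlation (adjusted p = 0.00535, 0.0425 and 0.0425). 12 of 20 flagellar genes (16 adjusted over the list alone, median -0.29, adjusted p = 1.23e-10) and the transporter genes ugpA and ugpB of the sugar transport list (2 of 4, 3 adjusted over the list alone, adjusted p = 0.00299) were lower. These also held with an estimated correlation (adjusted p = 0.0497 and 0.0425), but against the other substrates without glycerol their medians were 0.02 and -0.02 (adjusted p = 0.748 each), and 1 of the 2 transporter genes lost its call without xylose replicate 2 (ugpA, adjusted p = 0.0647) or xylose replicate 4. None of the 11 nitrogenase genes was called. Over all probe sets 329 were called, 130 higher and 199 lower, 64 of them by a log2 of at least 1 (46 and 18), and the count was 219 without xylose replicate 4.

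With glycerol (2 arrays) genes for glycerol breakdown and for flagella were higher than the mean of the other 4 substrates. Nitrogenase genes were lower, although their list was not called with an estimated correlation and several of its genes depended on single glycerol arrays. glpD (3613, glycerol-3-phosphate dehydrogenase) was 15.2-fold higher (log2 3.92 ± 0.10, SE, adjusted p = 1.27e-12), with levels of 11.95 ± 0.36 (SD, n = 2) with glycerol and 7.95 in the reference. kduI (1368) was at least 8.83-fold higher (3.14 ± 0.21), motA (1101, motor stator) at least 8.63-fold (3.11 ± 0.17), flgG (943) at least 8.03-fold (3.01 ± 0.18) and flgB (949, flagellar rod) 6.81-fold (2.77 ± 0.25). nifH (1431) was 2.15-fold lower (-1.11 ± 0.21, adjusted p = 0.00205) and nifA (1437) was lower by -0.48 ± 0.07 (adjusted p = 0.000294), and both calls held whichever array was left out.

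18 of 20 flagellar genes were higher (19 adjusted over the list alone, median 1.17, adjusted p = 2.39e-25, and adjusted p = 0.0106 with an estimated correlation). Against lactate, succinate, glucose and xylose alone 18, 17, 18 and 17 of them were higher. The sugar transport list was called through its 3 ugp genes (median 0.78, adjusted p = 0.000691, and adjusted p = 0.0182 with an estimated correlation), ugpB (4242) being higher by 1.76 ± 0.06, and of the 2 genes for glycerol use glpK (3605) was higher by 1.20 ± 0.07. 4 of 5 Entner-Doudoroff genes were higher (median 0.91, adjusted p = 0.000544, and adjusted p = 0.0830 with an estimated correlation), eda (3588, one of 2 loci) by 1.19 ± 0.14 and pgl (3678) by 1.08 ± 0.08.

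7 of 11 nitrogenase genes were lower (9 adjusted over the list alone, median -1.35, adjusted p = 1.67e-05, and adjusted p = 0.343 with an estimated correlation). Without glycerol replicate 1 the count was 4 and without glycerol replicate 2 it was 2, and nifB (1436, at -1.86 ± 0.38), nifS (1420, at -1.70 ± 0.33), nifN (1427) and nifD (1430) were then not called (adjusted p = 0.0735, 0.0865, 0.177 and 0.235), nor was nifE (1428) without glycerol replicate 1 (adjusted p = 0.0851). nifN, nifD and nifE lost their calls without either glycerol array. Against glucose, lactate, succinate and xylose alone 7, 5, 4 and 4 nitrogenase genes were lower, nifH against lactate by -1.20 (adjusted p = 0.00428). 4 of 5 hydrogenase maturation genes were higher (median 0.80, adjusted p = 0.0311) and 2 of 7 TCA cycle genes lower (gltA (2920, citrate synthase) and fumC (3072, fumarase), median -0.33, adjusted p = 0.0335), with adjusted p = 0.343 and 0.401 with an estimated correlation. Both counts were 0 without glycerol replicate 2, and 1 TCA cycle gene was called without glycerol replicate 1. The TCA cycle list was not called with a replicate block (-0.29, adjusted p = 0.0740) or against all probe sets (adjusted p = 0.0699), and 0 hydrogenase maturation genes were called between glycerol and xylose. Over all probe sets 673 were called, 335 higher and 338 lower, 153 of them by a log2 of at least 1 (127 and 26), 370 without glycerol replicate 1 and 277 without glycerol replicate 2. The share called higher was 49.8%, but 34.3% with centred arrays and 39.7% after quantile normalization.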

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

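The tests on cell density and on single deviating arrays were chosen only after the results they bear on were seen, those on brightness and on splits of the arrays before. In the glucose and xylose groups, the only ones with 4 arrays, 280 sets of 4 values of named probe sets or list medians were examined. In 12 of them, all of genes, 1 array lay far from the other 3, while chance gives 14 (about 1 in 20). The measure is the gap to the nearest array over the whole range, beyond its 95% critical value. Glucose replicate 2 was high in gcvT (ratio 0.885, 9.88 against 8.84 to 8.96), rpsN (0.872, 12.56 against 11.62 to 11.74) and phaC (0.921) and low in glpK (0.963, 9.08 against 9.34 to 9.35) and pufA (0.889). Glucose replicate 3 was high in chrR (0.903, 9.51 against 8.89 to 8.95), flgM (0.850) and ccoO (0.846), and glucose replicate 4 was low in thiM (0.889). Of the xylose arrays, replicate 1 was low in pufQ (0.882, 11.67 against 12.27 to 12.35), replicate 2 high in feoB (0.830, 10.91 against 9.97 to 10.13) and replicate 4 high in zwf (0.833, 11.68 against 11.50 to 11.53).

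12 named genes were called higher than the reference with one substrate and lower with another, and were also called by the F test. For each of them the difference between its highest and its lowest substrate is given. Genes and pairs were picked from these same values, so a called difference was nearly fixed in advance. The adjusted p-values of these differences are therefore no separate evidence. Glycerol exceeded glucose in flgM (log2 3.62 ± 0.24, SE, adjusted p = 5.17e-08), flgG (3.58 ± 0.21, adjusted p = 1.01e-08), flgB (3.37 ± 0.28, adjusted p = 7.62e-07), flgC (2.49 ± 0.14), flgH (2.31 ± 0.08, adjusted p = 4.67e-11) and fliD (1.59 ± 0.09). It exceeded lactate in glpK (1.25 ± 0.09) and fliQ (1.08 ± 0.06, adjusted p = 2.58e-09). xylF was higher with glucose than with lactate (4.44 ± 0.24), eda (3588, one of 2 loci) and zwf were higher with xylose than with lactate (2.19 ± 0.14 and 1.70 ± 0.09, adjusted p = 8.83e-09), and ispD was higher with lactate than with xylose (1.03 ± 0.14, adjusted p = 0.000233). Some falls below the reference were fragile. flgB with glucose lost its call without any 1 of 16 arrays (adjusted p = 0.204 without reference replicate 1) and flgG with glucose without either reference array (adjusted p = 0.136 without reference replicate 1). Without reference replicate 1 eda (3588) and zwf lost theirs with succinate (adjusted p = 0.0699 and 0.120) and with lactate (adjusted p = 0.0684 and 0.0850), so for these 4 genes no called fall was then left. With lactate flgM, fliQ, fliD and flgH also lost theirs without reference replicate 1, while the falls of flgM and flgH with glucose stayed called whichever array was left out.

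Ribosomal protein genes were higher in H2-producing cultures than in the reference. A shift of bright probe sets by the authors' normalization is argued against, since the list's median of 0.93 lay at percentile 100 of 10000 random lists matched on mean level, the highest of which reached 0.69. Cell density as the whole cause is argued against too, since 41 genes were called with density as a covariate. Culture volume cannot be told apart from nitrogen source, because 0 glutamate arrays were grown at the volume of the reference, and nitrogen source itself stays open. Glutamate and NH4+ cultures at one volume would test them.

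Flagellar genes were higher with glycerol than with the other substrates. 1 deviating glycerol array is argued against, since at least 17 of the 20 genes were called whichever glycerol array was left out, and so is cell density, with 18 called when density was a covariate. Glycerol itself may raise these genes, which stays a hypothesis from 2 arrays. Motility assays and further glycerol cultures would test it.

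Nitrogenase genes were higher with glucose (median 0.57). 1 deviating glucose array as the whole cause is argued against, since the second-highest glucose array exceeded the highest array of the other substrates by 1.015 in the list's median (SD within their groups 0.171), whereas a count of called genes, tried first, fell from 6 to 4 without glucose replicate 1 or 4 and decided nothing. The list's median fell by 1.34 ± 0.231 (SE) per 100 Klett units within the glucose cultures, and the slope in xylose was 0.25 ± 0.324. The xylose slope alone decided nothing, with 221 Klett units as its lowest density. The difference of slopes, 1.59 ± 0.398 or 4.00 standard errors, argues against a density effect alike in both sugars. It was tried after that, with the high values of the 2 low glucose cultures already seen, so the 4.00 overstates the evidence. An effect confined to densities below those of the xylose cultures was not tested. Without the arrays below 250 Klett units the difference shrank to 0.0746, so low density within the glucose cultures, or whatever set those 2 cultures apart, may account for most of the list's rise, while nifB, nifE, nifS and nifA stayed called. An effect of glucose itself stays open, and cultures of both sugars harvested at matched densities would test it.

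The 16 H2-producing arrays were split at random into groups of the same sizes, 100 splits per count with the real one included. As many calls came in 1 split (the real one) for any difference between the substrates (987, highest other 143). The same held for lactate (485 and 183), succinate (144 and 108), glucose (608 and 5) and glycerol (673 and 30). An arbitrary grouping is thus argued against for the F test. The other splits mix the substrates, which adds their differences to the spread within groups. They therefore cannot test the count of a single substrate. For xylose it was 2 of the 100 (329 and 434), and the split with 434 gave the xylose label to 2 lactate and 2 succinate arrays. That count, above the real one, points to a structure of the samples, the organic acids against the rest. The highest splits for lactate and succinate held both glycerol arrays.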

How the results depend on the processing

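Most results kept their direction and their side of the threshold. Apart from leaving out arrays, 108 of 152 counts stayed within 1.5 times the reported one. Of 6002 values of named genes 5643 stayed called or uncalled as before (272 lost their call, 67 gained one, 20 changed direction). So did 1378 of 1493 list results (63, 48 and 4). Results called in neither fit are among those kept, here and below, so the losses are not a share of the calls. With 1 array left out 197 of 216 counts, 9683 of 10278 gene values (563 lost, 32 gained) and 1842 of 1890 list results (36 and 12) were kept, and no called direction changed. Signal over background limits what can be called among dim probe sets, and background levels were not analysed here. Unless stated, the cause was not tested.

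Counts below are in the order mean of the substrates over the reference, then succinate, lactate, glucose, xylose and glycerol over the reference, then lactate, succinate, glucose, xylose and glycerol against the other substrates, then the F test. With only probe sets of 1 gene, fewer being tested, they were 305, 233, 232, 315, 266, 268, 105, 20, 141, 60, 91 and 163. With a log2 of at least 1 they were, by the stricter limit, 266, 244, 247, 343, 339, 333, 79, 39, 55, 64, 153 and 298. At an adjusted p under 0.01 they fell for the same reason to 1153, 702, 667 (succinate and lactate over the reference), 938 (glycerol over the reference), 241, 66, 289, 184, 353 and 577. Array weights, lowest for glucose replicate 2 (0.232) and highest for glucose replicate 4 (3.45), raised them to 1899 and 1849 (succinate and lactate over the reference), 805, 297, 1285, 1015 (lactate, succinate, glucose and glycerol against the others) and 1772 (F test). 17 were called for lactate against succinate alone, 402 for glucose without the 4 sugar arrays below 250 Klett units and 546 for xylose with density as a covariate.

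With a replicate block the counts were 1682, 1131, 1105, 1613, 1439, 1511, 483, 118, 536, 310, 547 and 840. Of 571 results for named genes 31 lost their call and 0 gained one, and of 105 list results 2 lost and 2 gained theirs. Whether replicate numbers pair the arrays stayed open: over 37 pairs of the same number the correlation of residuals, taken across probe sets, ran from -0.386 to 0.537 (glucose and xylose replicates 1), 14 exceeded 0.1, and 11 of 18 arrays correlated best with one of their own number.

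With 1 array left out the counts ranged from 859 to 1906 for the mean of the substrates over the reference, and from 597 to 1362, 562 to 1288, 996 to 1832, 874 to 1717 and 841 to 1702 for succinate, lactate, glucose, xylose and glycerol over the reference, each lowest without reference replicate 2. Against the other substrates they ranged from 257 (without lactate replicate 3) to 572, 67 (succinate replicate 2) to 193, 396 (glucose replicate 4) to 679, 219 (xylose replicate 4) to 435 and 277 (glycerol replicate 2) to 914, and for the F test from 756 (glycerol replicate 2) to 1192 (glucose replicate 2).

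Directions changed only where the group on the other side changed. Glucose against succinate alone had eda (3588) at 0.735 (adjusted p = 0.00489), zwf at 0.531 (0.00233), pgi at 0.343 (0.0147), pgl at 0.30 (0.0255), glpD at 0.052 (0.819) and ugpE at 0.012 (0.942), with the Entner-Doudoroff list at 0.343 (0.00519). Xylose against succinate had glpK at 0.056 (0.768), and glycerol xylB at 0.198 (0.726). Against the others without glycerol, chosen after seeing the data, succinate had flgH at 0.326 (0.00567), fliQ at 0.104, ugpB at 0.09, glpK at 0.033 and glpD at 0.011, the flagellar list at 0.216 (7.76e-13) and sugar transport at 0.0278. Glucose had glpD at 0.081 and ugpB at 0.019, and xylose had glpK at 0.107, ugpA at 0.018, flgM at 0.017, flgH at 0.006 and motA at 0.003, with flagella at 0.0183. By construction the changes in this last setting come from leaving glycerol out.

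The nitrogenase list with glucose lost its call with density as a covariate (0.18, adjusted p = 0.112) and against succinate alone (0.335, adjusted p = 0.0711). With that covariate it was called higher for lactate (0.66, adjusted p = 0.00269) and succinate (0.54, adjusted p = 2.03e-05) and lower for xylose (-0.45, adjusted p = 0.0240). It also gained calls without the 4 sugar arrays below 250 Klett units (lactate 0.52, adjusted p = 0.00717, and succinate 0.42, adjusted p = 0.00013), for succinate with a replicate block (0.33, adjusted p = 0.0198) and for xylose against the others without glycerol (-0.51, adjusted p = 0.0373). The ATP synthase and Entner-Doudoroff lists for succinate over the reference lost their calls with array weights (adjusted p = 0.0701 each), with density as a covariate (0.0808 and 0.110) and without the 4 sugar arrays (0.0579 each), the first also without the dimmest 25% of probe sets (0.0522) and the second with a replicate block (0.0586). The other list ended by that block was the TCA cycle with glycerol (-0.29, 0.0740).

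With all probe sets as background, chosen after seeing the data, lists of the mean of the substrates over the reference gained calls for hydrogenase maturation (adjusted p = 0.00263), respiratory chain (0.00178), ATP synthase (0.00558), flagella (0.0224) and Entner-Doudoroff (0.0428), and heat shock lost its call (0.110). For succinate over the reference hydrogenase maturation (0.00532) and the respiratory chain (0.00635) gained calls, and Entner-Doudoroff (0.193) and heat shock (0.0634) lost theirs. Against the other substrates sugar transport and ribosomal proteins with lactate (0.0436 each), hydrogenase maturation (0.0295) and flagella (0.00522) with succinate and pigments with glycerol (0.00428) gained calls, and the TCA cycle with glycerol lost its call (0.0699). With fry, which tests a list without a background, lists over the reference only gained calls, among them hydrogenase maturation (3.08e-06) and ATP synthase (1.15e-06) for the mean of the substrates, while the TCA cycle with succinate (0.142) and ribosomal proteins with glucose (0.0813) lost theirs.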

Other observations

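13 further gene lists were chosen after seeing the values and tested in 7 comparisons, adjusted over all 91 tests. Of 6 genes for isoprenoid precursors, 5 were higher with lactate than with the other substrates (median log2 0.64, adjusted p = 0.00385), 0 were called with succinate in a list called higher (0.24, adjusted p = 0.0133), 5 were lower with glucose (-0.49, adjusted p = 0.0168) and 5 were lower with xylose (-0.55, adjusted p = 0.00152). Each comparison is with the mean of the other substrates, so opposite signs are partly built in. ispD, 1 of these 6, had been seen to differ before the list was chosen, and the thiamine list is left out because 3 of its 4 genes had been. The 4 genes for the cofactor PQQ were higher with glycerol (0.88, adjusted p = 0.000419) and lower with lactate (-0.34, adjusted p = 0.0133), the list was also lower with succinate with 1 gene called (-0.29, adjusted p = 0.0168), and 4 of 8 haem genes were lower with glucose (-0.30, adjusted p = 0.0370). Over the reference, 13 of 14 aminoacyl-tRNA synthetase genes rose in the mean of the substrates (0.54, adjusted p = 0.0133) and in succinate (0.49, adjusted p = 0.0117), beside the ribosomal protein genes. With an estimated correlation none of these lists was called, with adjusted p from 0.498 to 0.676.

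Most probe sets carry no gene name, and some of those changed as much as the nitrogenase genes. Probe sets 4140 and 2671, singled out after their values were seen, were higher in the mean of the substrates than in the reference by log2 5.05 ± 0.31 (SE, adjusted p = 1.36e-07) and 3.95 ± 0.30 (adjusted p = 7.39e-07), and 4576 and 3448 were lower by -3.77 ± 0.45 (adjusted p = 2.19e-05) and -2.98 ± 0.17 (adjusted p = 5.59e-08). Probe set 4140 in the reference (7.445) and 4576 in the mean of the substrates (6.693) lay below the lower quartiles. The sizes of these 2 differences are therefore lower bounds.

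Of the 10 genes with several probe sets, some gave a single answer over the reference: all 5 probe sets of appA (0.59 to 0.82) were called higher, and none of the 5 of ppsR (-0.14 to 0.15) was called. The probe sets of fnrL spanned 0.38 to 0.65 with 2 of 5 called, those of rpoB 0.30 to 1.00 with 2 of 2 called, and those of fabG 0.17 to 1.34 with 1 of 2 called.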
